A study of Vitis vinifera with 24 samples.

How the data were processed

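RNA was measured in 24 non-directional sequencing libraries from grapevine (Vitis vinifera), 3 from each of 8 groups. The groups were anthers, undifferentiated callus at day 40 of culture (40D), non-embryogenic callus (NEC) and embryogenic callus (EC) of the cultivars Cabernet Sauvignon (CS) and Sangiovese (SG). The labels call the replicates biological. Per the submitters' processing notes, the tools were CASAVA 1.8.2, TopHat2 2.0.9 and Cufflinks 2.1.1. The genome build and the annotation are not given in the sources used here.

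The authors deposited FPKM values, fragments scaled to transcript length and to the number of mapped fragments, for 29971 loci with 1 column per library. Whether they scaled the libraries further is not given in the sources used here. FPKM is not a count, so no count model was used. The column sums ran from 729402 to 938765. The number of reads per library is unknown, and the relative depth was estimated from the most frequent ratio of low values, under 0.15 FPKM, to those of the first CS anther library. It ran from 0.889 to 1.51. An exact 0 can be a failed estimate: 130 loci were listed at 0 in one library and at 10 FPKM or more in another of the same group. No pair of libraries held identical values.

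Loci with 1 FPKM or more in at least 3 libraries were tested, which left 21568. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group, all libraries in one fit, 16 residual degrees of freedom and a trend of the spread with expression. Adjusted p is the Benjamini-Hochberg value within a comparison from this limma fit, and loci with an adjusted p under 0.05 are counted as higher or lower. Fold changes are on the log2(FPKM + 1) scale, which understates the change of loci with low values. Groups, tests, gene lists and most alternatives were fixed before the data were examined.

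The locus identifiers come without names or descriptions, and 0 of them matched the reference gene table. The 38 gene lists and 7 lists of cell type markers that had been written as words to be found in descriptions could therefore not be used. No marker of another cell type was tested. The 3 remaining lists were written as locus numbers: 54 stilbene synthase loci, 14 flavonoid pathway loci and 10 floral organ MADS-box loci. Their identity rests on published locus assignments and not on the files. The stilbene synthase pattern also took in 5 loci outside the range meant, so its main counts are given for the restricted range of 49 loci as well. Stilbene synthase loci are near-identical copies that may share reads, and the value of any one of them is uncertain. Lists were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 39 tests. The estimated correlation was 0.67 for stilbene synthase, 0.55 for flavonoid pathway and 0.22 for MADS-box loci, all far above the preset value. The fry test of limma, planned with them, was adjusted in the same way. It asks whether list members changed and does not compare them with other loci. As 79.4% of all tested loci were called in CS EC against NEC, a low p from fry does not set a list apart.

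The rule for named loci took those with the largest changes among loci past the threshold, with 5 FPKM or more in the higher group and no overlap between the compared libraries. It also asked for a description, a condition that could not be applied. The planned rule asked for more loci each way in every comparison, and this was cut to 2 each way. All are given for EC against NEC, and some or none for the other comparisons. Loci with the intermittent zeros described above were passed over, a choice made after the data were examined that replaced 7 of the 48 loci named in comparisons of 2 groups. List members are those with the smallest adjusted p.

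The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, the replicate number as a block, a fit of the compared groups alone, median-of-ratios scaling, rescaling to equal sums, robust moderation, a log2 fold change of at least 1, and leaving out each replicate. Others were added after the data were examined: the restricted stilbene synthase range, leaving out together SG EC replicate 1 and SG NEC replicate 2, which had the most signal of the other callus type in their groups, and each 40D group averaged into 1 sample. The steps were tested on simulated data with 200 changed loci, drawn from those at 5 FPKM or more in NEC. Each locus had independent noise of the same size in all groups. In the data most loci were called and groups differed in spread, so the values below may not carry over. In simulated CS EC against NEC, over 21322 loci, 71.6% of 1.5-fold, 89.6% of 2-fold and 92.4% of 4-fold changes were recovered, and 14 unchanged loci were called. In the simulated interaction, over 20858 loci, these shares were 55.2%, 83.6% and 93.9%, with 9 unchanged loci called.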

Results

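Gene expression was measured during somatic embryogenesis of grapevine, the formation of embryos from cultured body tissue, in a cultivar labelled poorly competent (CS) and one labelled highly competent (SG). Anthers were cultured in the dark on a medium with the auxin 2,4-D and the cytokinin BAP. Callus was sampled at day 40, and at month 4 calli were classed under the microscope as embryogenic or non-embryogenic. Each of the 8 groups had 3 libraries.

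Anthers stood apart from all callus, and embryogenic callus stood apart from the other callus types. The first principal component, with 40.9% of the variance, separated anthers from callus. The second, with 32.1%, separated EC from the rest. Among tissues of the same cultivar, NEC was closest to 40D callus, with a mean correlation across loci of 0.943 in SG and 0.874 in CS, against 0.764 and 0.766 between EC and 40D. Across cultivars, CS NEC correlated at 0.922 with SG NEC and at 0.887 with SG 40D. Loci are not independent replicates.

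**Figure D1:**
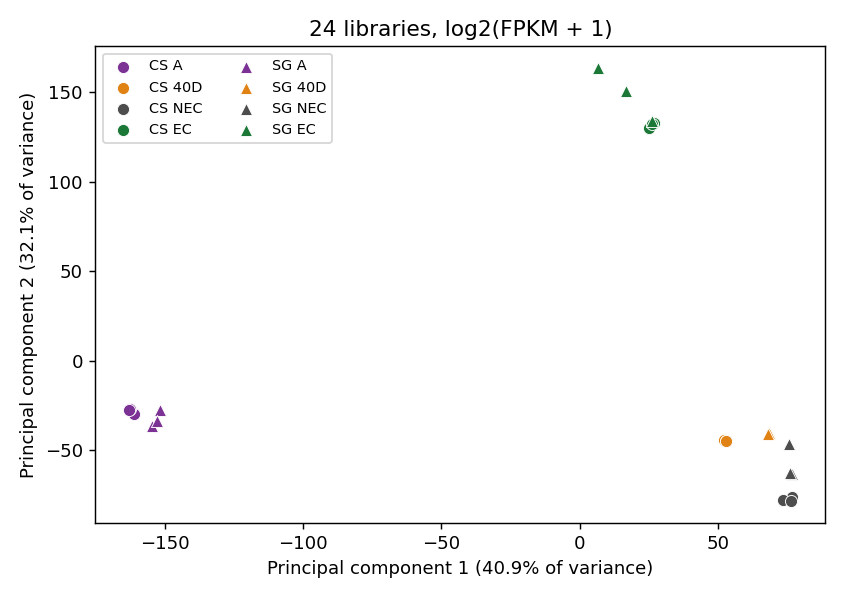
Scores of the 24 libraries on the first 2 principal components of log2(FPKM + 1), with colours for tissues, circles for CS and triangles for SG. Anthers lie at the left, and the EC libraries lie at the top, with the 3 SG EC libraries spread from 134.1 to 163.7 on component 2.

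The 3 libraries of each 40D group agreed more closely than those of other groups. Among loci of 1000 FPKM or more, the median coefficient of variation was 2.67% in CS 40D and 1.45% in SG 40D, against 6.51% to 12.6% in the other groups. The gap was narrower at lower levels: from 100 to 1000 FPKM it was 2.57% and 1.81%, against 3.23% in SG NEC, the next lowest, and from 10 to 100 FPKM 3.62% and 3.12%, against 4.17% there. All comparisons use a spread pooled over the 8 groups. Counts were also computed, after the data were examined, with each 40D group as 1 sample. That sample is assumed to vary like the other groups, from which the spread then comes, with 12 residual degrees of freedom. The labels call the 40D libraries biological replicates, and whether they came from separate calli or from 1 pool was not tested. From 1 pool, the SDs given for 40D describe the measurement alone, and adjusted p of comparisons with 40D are too low. In anthers and EC of both cultivars, replicate 3 lay between replicates 1 and 2 in the summed level of each list. Replicates 1 and 2 correlated least there, in SG EC at 0.9676, against at least 0.9856 with replicate 3. Whether the 3 libraries of these groups are independent was not tested. If replicate 3 is not, their SDs and adjusted p may be too low.

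**Figure D2:**
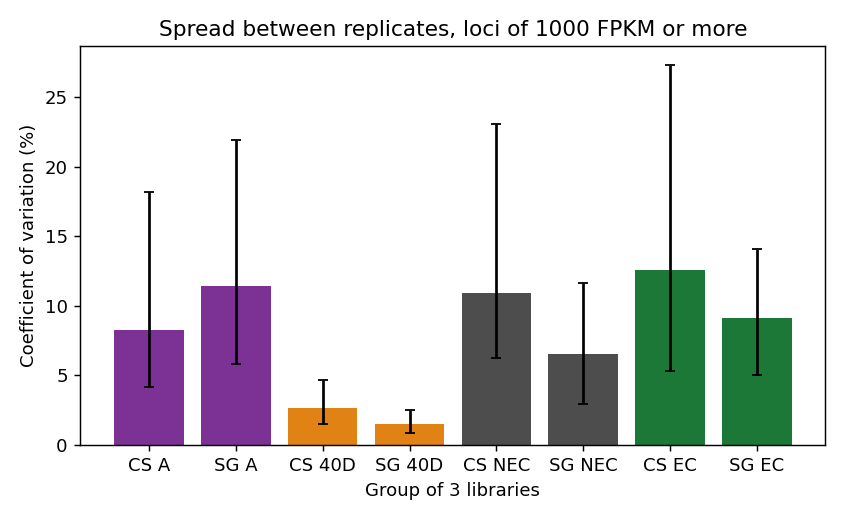
Median coefficient of variation in percent over loci of 1000 FPKM or more, for each group of 3 libraries, with error bars from the lower to the upper quartile of the loci. The bars of CS 40D, 2.67%, and SG 40D, 1.45%, are the lowest.

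The main comparison asked how embryogenic callus differed from non-embryogenic callus of the same cultivar. Most of the floral organ MADS-box loci, which encode transcription factors of flower development, and of the stilbene synthase loci, whose enzymes make resveratrol-type compounds, were lower in EC in each cultivar. As lists, neither passed camera with an estimated correlation, with an adjusted p of 0.52 for MADS-box and 0.84 for stilbene synthase loci in both cultivars. By fry, which does not compare lists with other loci, the adjusted p was 6.2e-09 for MADS-box loci in both. For stilbene synthase loci fry gave an adjusted p of 0.013 in CS and 0.15 in SG. The summed MADS-box level was 756 ± 58.0 FPKM in CS NEC and 51.3 ± 25.8 in CS EC (SD, n = 3). In SG it was 766 ± 44.2 in NEC and 84.5 ± 17.4 in EC. Stilbene synthase loci summed to 1089 ± 165 FPKM in SG NEC and 122 ± 41.5 in SG EC. In CS the EC sum was 163 ± 15.1, while the NEC libraries gave 473.9, 450.4 and 3034, so 1 library decided the NEC mean. Most of the EC sums came from the 5 loci outside the range meant for this list: without them the sum was 72.1 ± 5.45 FPKM in CS EC, and in SG 1048 ± 169 in NEC and 41.7 ± 44.0 in EC, where the libraries stood far apart at 89.6, 3.18 and 32.4.

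Of the 10 MADS-box loci, 6 fell and 1 rose in CS, and 7 fell and 0 rose in SG, with 3 not called in each. Adjusted over the list alone, 0 rose in CS, and the 1 rise was also lost under median-of-ratios scaling. VIT_18s0041g01880 fell by 4.50 in CS and by 4.31 in SG on the log2 scale, with a standard error of 0.24. VIT_14s0083g01050 fell by 3.44 in CS, from 22.4 ± 5.93 to 1.19 ± 0.697 FPKM, while SG had 51.7 ± 0.776 in NEC and 55.4 ± 5.82 in EC. The camera test gave an adjusted p of 0.0052 in CS and 0.0057 in SG, and an adjusted p of 0.52 in both with an estimated correlation.

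Of the 41 stilbene synthase loci tested, 30 fell, 3 rose and 8 were not called in CS, and 23 fell, 2 rose and 16 were not called in SG. In the restricted range of 36 tested loci, 29 fell in CS and 21 in SG, and 0 rose in either. VIT_16s0100g01100 fell by 6.26 in SG, with a standard error of 0.62. Its SG EC libraries stood far apart, at 20.4, 0.774 and 7.67 FPKM. VIT_16s0100g00710, one of the loci outside that range, rose by 3.21 in CS and 3.80 in SG, with a standard error of 0.14. The camera test gave an adjusted p of 6.4e-05 in CS and 0.0043 in SG, and an adjusted p of 0.84 in both with an estimated correlation.

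Counts of flavonoid pathway loci differed between the cultivars, and the test of that difference is given with the interaction below. In CS 7 of 14 rose and 3 fell, and in SG 1 rose and 8 fell. Of all 21568 tested loci, 11091 were higher and 6028 lower in CS EC, so the CS rises were near the share of all loci. In SG EC 9948 of all loci were higher and 6937 lower. Under median-of-ratios scaling 3 rose in CS, and with the compared groups alone in the fit 4 rose. VIT_18s0001g12800 fell by 1.12 in CS and by 2.82 in SG, with a standard error of 0.11. VIT_00s0361g00040 rose by 1.96 in CS, with a standard error of 0.20. The camera test gave an adjusted p of 0.67 in CS and 0.022 in SG, the latter 0.84 as an adjusted p with an estimated correlation. Adjusted p from fry was 0.6 in CS and 6e-05 in SG.

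**Figure D3:**
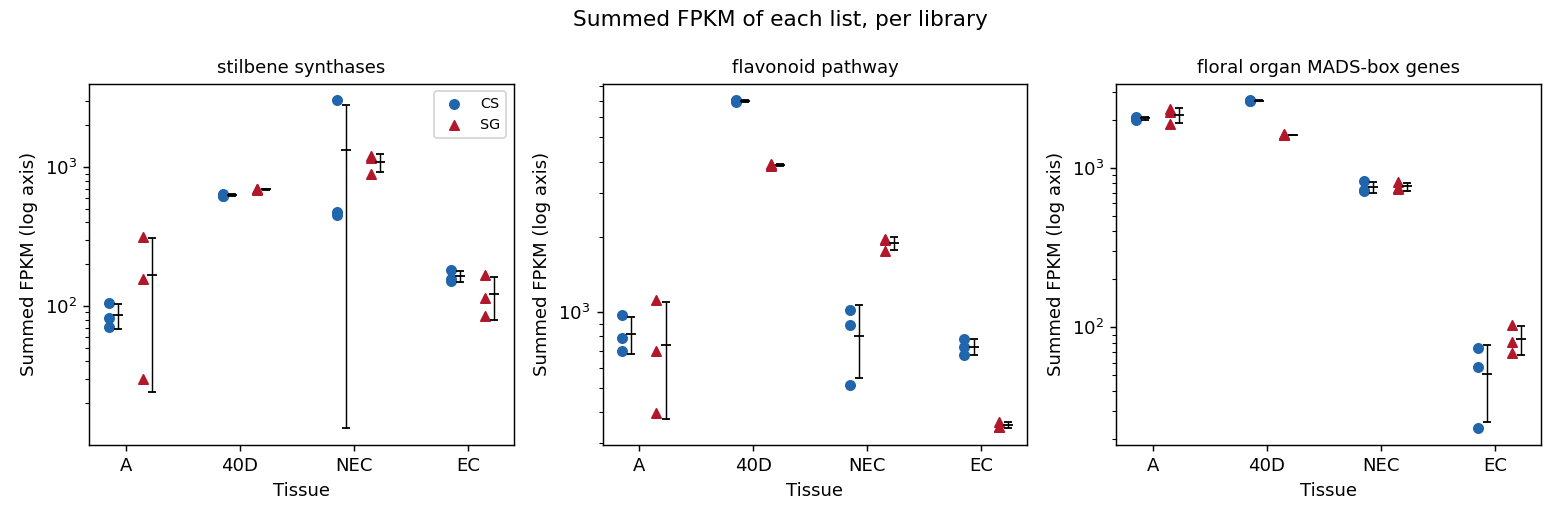
Summed FPKM of the loci of each list on a log axis, for each library of the 4 tissues, with circles for CS and triangles for SG and black marks for the mean and SD of 3 libraries. The MADS-box sums are lowest in EC, and the flavonoid pathway sums are highest in 40D.

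Over all loci, 11091 were higher and 6028 lower in EC than in NEC of CS, and 9948 were higher and 6937 lower in SG. Of these, 5620 and 3108 in CS, and 4751 and 3574 in SG, changed by at least 1 on the log2 scale. The share of higher loci was 64.8% in CS and 58.9% in SG as deposited, and 52.2% and 52.1% after median-of-ratios scaling. The median log2 fold change over all loci was 0.31 in CS and 0.16 in SG, and changes are to be read relative to it. In its group, SG EC replicate 1 had the most signal of NEC loci and SG NEC replicate 2 the most of EC loci, and without both 9381 loci were higher and 6716 lower in SG.

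The files do not pair locus identifiers with names. In CS, VIT_07s0130g00030 went from 0.0347 ± 0.0600 FPKM in NEC to 221 ± 139 in EC, and VIT_10s0003g03490 from 0.262 ± 0.0749 to 224 ± 72.9. The first of these was listed at 0 in NEC replicates 1 and 2, and was at 145 FPKM in EC without replicate 2. VIT_06s0004g02560 fell from 6046 ± 1780 to 1.28 ± 0.244 FPKM, and VIT_05s0049g00520, at 15720 ± 856 FPKM in NEC, fell by 10.51 on the log2 scale, with a standard error of 0.53. In SG, VIT_06s0004g04210 rose from 0.614 ± 0.479 to 955 ± 238 FPKM, and VIT_09s0002g02450 from 0.892 ± 0.278 to 497 ± 190. VIT_02s0025g04300 fell by 8.39 on the log2 scale, with a standard error of 0.59, to 33.9 ± 33.6 FPKM, and VIT_02s0025g04310 fell from 6178 ± 90.1 to 35.9 ± 38.2. Without SG EC replicate 1, which had the most signal of NEC loci, these 2 were at 15.6 and 14.9 FPKM in EC, and without SG NEC replicate 2 VIT_06s0004g04210 was at 0.374 FPKM in NEC.

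The loci changed in the cultivars overlapped. A total of 8734 loci were higher in EC in both, where independent lists would share 5116, and 4946 were lower in both, where independent lists would share 1939. The odds ratios from Fisher's exact test were 28.3 and 31.1, and 796 loci went in opposite directions. The comparisons share no EC or NEC libraries, but both use the same pooled spread for each locus, which can raise the overlap. With the compared groups alone in the fit, 8643 loci were higher and 4823 lower in both.

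The interaction asked whether the EC to NEC difference itself differed between cultivars. Flavonoid pathway loci fell further, or rose less, in SG than in CS: 11 of 14 had a lower and 1 a higher difference in SG. The camera test gave an adjusted p of 0.0074, and an adjusted p of 0.84 with an estimated correlation. Adjusted p from fry was 0.00032. The MADS-box locus VIT_14s0083g01050 had a difference of 3.54, with a standard error of 0.26 and a limma adjusted p of 4.14e-09, and VIT_18s0001g01760 one of -3.98, with a standard error of 0.51. Among stilbene synthase loci, 3 had a higher and 3 a lower difference, and adjusted over the list alone 1 had a higher one. In the restricted range 2 had a higher and 1 a lower difference.

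Over all loci the difference was higher in SG for 3268 and lower for 6867. The share of higher loci was 32.2% as deposited and 49.7% after median-of-ratios scaling. VIT_05s0094g00350 was at 661 ± 241 FPKM in CS NEC and 1.27 ± 0.726 in CS EC, and in SG at 0.443 ± 0.0692 and 0.587 ± 0.220. VIT_14s0128g00670 was at 3.29 ± 1.31 FPKM in CS NEC and 15.9 ± 12.8 in CS EC, and in SG at 16.9 ± 6.63 and 0.0831 ± 0.0301. Its CS EC mean was 9 FPKM without replicate 2, which had 29.8.

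The comparison of 40D callus with anthers asked what changed as callus formed. Most flavonoid pathway loci rose, with 13 of 14 higher and 1 lower in CS and 12 higher and 1 lower in SG, or 12 and 9 higher with each 40D group as 1 sample. The camera test gave an adjusted p of 0.0016 in CS and 0.0039 in SG, and an adjusted p of 0.73 and 0.80 with an estimated correlation. Fry gave an adjusted p of 6.4e-08 in CS and 2.3e-07 in SG. Their sum went from 820 ± 138 to 6964 ± 60.9 FPKM in CS and from 738 ± 363 to 3881 ± 36.7 in SG. VIT_17s0000g07200 rose by 5.71 in CS and 4.50 in SG, with a standard error of 0.22.

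Of the 41 stilbene synthase loci, 26 rose and 1 fell in CS, and 19 rose and 6 fell in SG. Taking each 40D group as 1 sample, 22 rose and 1 fell in CS, and 13 rose and 0 fell in SG. The 6 falls in SG depended on single libraries: 13 loci fell without SG anther replicate 1, 0 without replicate 2 or replicate 3, and 3 without SG 40D replicate 1 or replicate 2. In the restricted range of 36 tested loci, 23 rose and 0 fell in CS, and 16 rose and 6 fell in SG. VIT_16s0100g01100 rose by 7.44 in CS and 6.65 in SG, with a standard error of 0.62. For the full list the camera test gave an adjusted p of 0.0016 in CS, and of 0.84 with an estimated correlation. In SG camera gave an adjusted p of 0.11. Adjusted p from fry was 0.011 in CS and 0.26 in SG.

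The MADS-box loci did not move one way. In CS 2 rose and 3 fell, and in SG 1 rose and 6 fell, with camera adjusted p of 0.91 and 0.40. Fry gave an adjusted p of 0.018 in CS and 0.00091 in SG. The rises and falls were 1 and 3 in CS, and 1 and 4 in SG, with each 40D group as 1 sample. Their sum was 2051 ± 40.8 FPKM in CS anthers and 2639 ± 21.9 in CS 40D callus, and 2161 ± 233 and 1615 ± 5.72 in SG. VIT_18s0041g01880 rose from 0.513 ± 0.0665 to 74.2 ± 1.32 FPKM in CS and from 0.639 ± 0.230 to 20.2 ± 1.64 in SG. VIT_01s0011g00100 fell by 2.62 in CS and also fell in SG. One of the 2 rises in CS was lost whenever any single library of either group was left out.

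Over all loci, 7675 were higher and 9281 lower in 40D than in anthers of CS, and 7936 higher and 8611 lower in SG. Median-of-ratios scaling turned the balance, to 8757 higher and 8220 lower in CS and 8739 and 7834 in SG, while equal sums gave 6201 and 10827 in CS and 6224 and 10491 in SG. With each 40D group as 1 sample, 14630 in CS and 14042 in SG passed the threshold. VIT_15s0021g02170 fell from 4793 ± 685 to 1.65 ± 1.09 FPKM in CS and from 4595 ± 367 to 1.30 ± 0.787 in SG. VIT_01s0011g05150 rose from 1.93 ± 0.818 to 2392 ± 34.7 FPKM in CS, and VIT_05s0049g00600 from 0.434 ± 0.339 to 3155 ± 77.1 in SG. The low levels rest on few libraries: VIT_15s0021g02170 was at 1.09 FPKM without CS 40D replicate 1 and at 0.849 without SG 40D replicate 3, and VIT_05s0049g00600 at 0.243 without SG anther replicate 3.

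From 40D to month 4 callus, most flavonoid pathway loci fell on both routes, as did most MADS-box loci except in SG NEC. In EC against 40D, 12 of 14 flavonoid pathway loci fell in CS and 14 in SG, and 9 of 10 MADS-box loci fell in each. In NEC against 40D, 13 flavonoid pathway loci fell and 1 rose in CS, and in SG 9 fell and 5 were not called, while 8 MADS-box loci fell in CS, and in SG 5 fell, 1 rose and 4 were not called. With an estimated correlation the lowest of these adjusted p from camera was 0.38. Those from fry ran from 1.2e-12 to 0.00032. With each 40D group as 1 sample, 11 and 12 flavonoid pathway and 8 and 7 MADS-box loci fell in EC of CS and SG, and 13 and 6 flavonoid pathway and 5 and 3 MADS-box loci fell in NEC. Stilbene synthase loci fell in EC, 26 in CS and 21 in SG with 2 higher in each, and in NEC 2 fell and 1 rose in CS and 1 fell and 1 rose in SG. In the restricted range 24 fell in CS EC and 20 in SG EC, with 0 higher in either. In NEC that range had 1 rise in CS and 0 loci called in SG. For the full list in EC, camera gave an adjusted p of 0.00019 in CS and 0.0027 in SG, both 0.84 with an estimated correlation. Adjusted p from fry was 0.057 and 0.11. In EC 15 stilbene synthase loci fell in each cultivar with each 40D group as 1 sample.

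EC against 40D gave 11207 higher and 5713 lower loci in CS and 10231 higher and 6402 lower in SG, with 53.1% and 51.4% higher after median-of-ratios scaling against 66.2% and 61.5% as deposited. NEC against 40D gave 6901 higher and 6738 lower in CS and 5534 higher and 4701 lower in SG. In SG the balance turned to 4571 higher and 5525 lower after median-of-ratios scaling, and equal sums gave 7059 and 3853. Among changes of at least 1 on the log2 scale, 822 were higher and 1387 lower in SG, and 2201 and 2254 in CS. With each 40D group as 1 sample, EC against 40D gave 14671 loci in CS and 14309 in SG, and NEC against 40D gave 10010 in CS and 5505 in SG.

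Cultivars were compared within each tissue. In NEC, 10 of 14 flavonoid pathway loci were higher and 1 lower in SG than in CS, and in EC 1 was higher and 7 lower. In 40D callus 7 flavonoid pathway loci were lower in SG and 0 higher, or 4 lower with each 40D group as 1 sample, and in anthers 5 were lower and 1 higher. All 4 had an adjusted p of at least 0.84 from camera with an estimated correlation. Adjusted p from fry was 0.0074 in NEC, 0.0085 in EC, 0.006 in 40D and 0.028 in anthers. The MADS-box list had 3 loci higher in SG in NEC and 0 lower, and 2 each way in EC.

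Over all loci, SG exceeded CS at 4315 loci and lay below it at 5067 in anthers, at 6650 and 5628 in 40D, at 6829 and 4682 in NEC, and at 4172 and 6920 in EC. These totals of 9382, 12278, 11511 and 11092 rest on the spread pooled over groups. With the compared groups alone in the fit they were 6450 in anthers, 15253 in 40D, 11497 in NEC and 9123 in EC. With each 40D group as 1 sample the 40D count was 5842 in all, in place of 12278, from 1 sample against 1 with the spread of the other groups. After median-of-ratios scaling the anther counts were 4689 and 4684, and the share of higher loci was 50.4% in 40D, 48.2% in NEC and 45.7% in EC, against 54.2%, 59.3% and 37.6% as deposited. Among differences of at least 1 on the log2 scale, 915 loci were higher and 861 lower in SG anthers, and 1331 and 1430 in SG NEC. VIT_02s0033g00420 had 462 ± 57.7 FPKM in SG EC and was listed at 0 in the 3 CS EC libraries.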

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

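The tests of anther tissue, of FPKM scaling, of mixed callus and of carried-over reads were chosen after the results they measure were seen, and the test of abundant loci and the other splits were chosen before. Differences between cultivars below were found by the interaction term in limma.

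The EC to NEC change differed between the cultivars at 4 of the 8 loci named for their size. Each was picked for its change in 1 cultivar and changed more in that cultivar, as such a choice favours. The other 4 did not differ, with adjusted p of 0.206, 0.256, 0.289 and 0.825, and 47.0% of all tested loci did. The difference, SG minus CS, was 3.71 at VIT_06s0004g02560, 3.79 at VIT_05s0049g00520, 3.99 at VIT_06s0004g04210 and 3.35 at VIT_09s0002g02450. Some of these levels rest on 1 library. Without CS EC replicate 2, VIT_06s0004g04210 was at 90.6 FPKM in CS EC in place of 224.7, and VIT_09s0002g02450 at 85.4 in place of 213.5. Without SG EC replicate 1, VIT_06s0004g02560 was at 2.31 FPKM in SG EC in place of 5.80, and VIT_05s0049g00520 at 4.10 in place of 7.32. Of list members, only those whose change differed past the threshold are listed. Among stilbene synthase loci the difference was 0.59 at VIT_16s0100g00710, -2.30 at VIT_16s0100g00740 and -3.51 at VIT_16s0100g01100. The first and second of these lie outside the range meant for that list. It was -1.70 at VIT_18s0001g12800, -1.54 at VIT_00s0361g00040 and -2.84 at VIT_13s0067g03820 of the flavonoid pathway, and 3.54 at the MADS-box locus VIT_14s0083g01050. Without CS NEC replicate 3, VIT_16s0100g01100 was at 85.6 FPKM in CS NEC in place of 173.3, and VIT_16s0100g00740 at 2.16 in place of 3.89. Without SG EC replicate 1, VIT_16s0100g01100 was at 4.22 FPKM in SG EC in place of 9.61. For the change from anthers to 40D, 49.5% of all tested loci differed between the cultivars, and again only loci past the threshold are listed. The difference was -2.72 at VIT_05s0049g00520, 2.67 at VIT_05s0049g00600 and -2.07 at VIT_01s0010g03720. Among list members it was -1.20 at VIT_17s0000g07200, -1.94 at VIT_18s0041g01880 and 1.12 at VIT_01s0011g00100.

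The summed level of floral organ MADS-box loci in 40D callus was 129% of that in anthers in CS and 74.7% in SG. Abundant members carry the sum, and members went both ways: in CS 2 rose and 3 fell, with VIT_17s0000g05000 going from 10.5 to 0.405 FPKM, and in SG 1 rose and 6 fell. The 5th percentile of the 40D to anther ratio over 1335 loci abundant in anthers was at most 0.44%. That argues against anther tissue that kept all transcripts of the sampled anthers. Tissue that lost some of them during culture cannot be excluded this way. Over these 1335 loci the median ratio was 65.5% in CS and 66.7% in SG, so the SG sum was near the usual level of such loci. After median-of-ratios scaling the lower of the 2 sums was still 81.3% of the anther level. The scaling factors of anther and 40D libraries lay between 0.896 and 1.034, so this step could not have moved the sums far. Persistence of particular anther cell types stays open, since no cell type marker could be matched, and expression of these loci in callus cells is a hypothesis.

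The 3 SG EC libraries differed in loci of non-embryogenic callus. Over 64 loci picked in CS as high in NEC, their medians were 5.59%, 0.345% and 2.55% of the SG NEC level. SG NEC replicate 2 showed the reverse: over 178 loci picked in CS as high in EC, its median was 4.47% of the SG EC level, against 1.49% and 1.54% in replicates 1 and 3. Its score on principal component 2 was -46.4, against -63.6 and -63.0. No cause of this was tested. Reads carried over from CS libraries were looked for at 11 loci, at 5 FPKM or more in CS NEC and 0.1 FPKM or less in SG anthers, 40D and NEC. Their median was 0% of the CS level in SG EC replicate 1. That argues against a carried share large enough to be seen at these loci. A smaller share could read as 0 at loci of such levels and cannot be excluded. A varying share of non-embryogenic callus may be the source, and cannot be told apart from a difference between the calli: loci high in EC were at 88.4% of the level in replicate 2, below the limit of 90% set for it, but pairs of CS EC libraries went as low as 88.2%. Carry-over within SG was not tested.

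More loci were higher than lower in EC against NEC. Leaving the 10 most abundant loci of each library out of the sum used for scaling left 64.3% higher in CS and 58.9% in SG, against 68.5% and 63.3% when all loci are rescaled to equal sums, so these loci alone do not account for it. Scaling in general cannot be told apart from a true excess, because median-of-ratios scaling, with 52.2% in CS and 52.1% in SG, sets the middle of all changes near 0 by its construction. An excess of active loci in embryogenic callus stays open.

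Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and in each of the 12 only the real split, 1 of 10, reached the real count. The highest other split gave 5 loci for CS EC against NEC and 7 for SG, 1 for 40D against anthers in both cultivars, 1 and 3 for EC against 40D, and 2 and 2 for NEC against 40D. Between cultivars it gave 1115 in anthers, 1 in 40D, 11 in NEC and 1721 in EC. Each of these other splits mixes libraries of both groups, which puts the group difference into the spread and lowers the count. The counts are therefore no measure of false calls. For the interaction, 2 of 100 splits drawn from 200, the real one among them, gave at least the real count of 10135. These splits exchange libraries between cultivars within EC and within NEC, so they test for any cultivar difference. Mixed splits also put that difference into the spread, which lowers their counts. They therefore cannot decide whether the interaction arose by chance. The highest other, with 12849, exchanged all NEC libraries between the cultivars and thereby measures the cultivar difference, and the next reached 7525.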

How the results depend on the processing

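Counts with each 40D group as 1 sample, with SG EC replicate 1 and SG NEC replicate 2 left out together and for the restricted stilbene synthase range were chosen after the data were examined. Counts of called loci stayed within 1.5 times of the reported ones under every alternative except the fold limit and, for 2 comparisons, 40D as 1 sample. Read numbers are unknown, so no limit from depth is given, and the causes of the changes below were not tested unless named.

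With the replicate number as a block, 17084 loci passed in CS EC against NEC and 16849 in SG, and the 1 MADS-box rise in CS became 0, while every other count here stayed within 1.5 times. No comparison had every same-number correlation of deviations from the group mean above 0.1. Between cultivars these were 0.16, 0.17 and 0.015 in EC and -0.26, -0.23 and -0.037 in anthers. In anthers and EC replicate 3 lay between the others in list sums, so its deviations may be too small to meet this rule. Of 24 libraries, 11 correlated best with their own number, and the number expected without pairing was not computed. Whether the numbers pair the libraries is therefore not settled.

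Asking also for a log2 fold change of 1 leaves fewer loci by its construction: 8728 and 8325 for EC against NEC in CS and SG, 3335 for the interaction, 8689 and 7627 for 40D against anthers, 8429 and 7633 for EC against 40D, and 4455 and 2209 for NEC against 40D. Between cultivars it left 1776 in anthers, 3225 in 40D, 2761 in NEC and 2678 in EC. The loci shared by the cultivars were 3797 higher and 2349 lower. It left 4 flavonoid pathway rises in CS EC against NEC, 0 MADS-box rises there, and 0 flavonoid pathway falls in SG 40D against anthers. With each 40D group as 1 sample, assumed to vary like the other groups, SG NEC against 40D gave 5505 and 40D between cultivars 5842. List counts became 1 higher stilbene synthase locus in the interaction, 0 stilbene synthase falls in SG 40D against anthers, 0 MADS-box rises in CS EC against NEC and 1 in CS 40D against anthers.

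Small list counts moved most. The 1 MADS-box rise in CS EC against NEC became 0 with a pseudocount of 0.1, no filter, the compared groups alone or median-of-ratios scaling. The 2 MADS-box rises in CS 40D against anthers became 1 with a pseudocount of 0.1 or equal sums. The 3 stilbene synthase loci with a higher interaction became 1 with a pseudocount of 0.1. The stricter filter tests fewer loci: in EC against NEC it left 1 stilbene synthase rise and 17 falls in CS and 1 rise in SG, and in the interaction 0 higher stilbene synthase and 0 higher flavonoid pathway loci. In 40D against anthers it left 1 stilbene synthase fall in SG, 0 flavonoid pathway falls in either cultivar, and 1 MADS-box fall in CS and 3 in SG. The compared groups alone gave 4 flavonoid pathway rises in CS EC against NEC and 2 in SG, and in 40D against anthers 0 stilbene synthase falls in SG, 5 MADS-box falls in CS and 2 MADS-box rises in SG. Median-of-ratios scaling gave 3 flavonoid pathway rises in CS EC against NEC, and equal sums gave 2 in SG. The restricted range gave 0 stilbene synthase rises in EC against NEC in both cultivars, 1 lower in the interaction and 0 falls in CS 40D against anthers.

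Without single replicates, MADS-box rises ranged from 0 to 1 in CS EC against NEC, from 1 to 1 in CS 40D against anthers and from 1 to 2 in the interaction. Stilbene synthase falls in SG 40D against anthers ranged from 0 to 13, higher stilbene synthase loci in the interaction from 1 to 4, and flavonoid pathway rises in SG EC against NEC from 1 to 2. Of the log2 fold changes of named loci, 0 reversed, and 6 of 1919 values under alternatives no longer passed the threshold.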

Other observations

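The count of neighbouring loci was chosen after the loci were seen. Tissues differed in how many loci passed a rule for being seen in 1 tissue only. In both cultivars, 66 loci were at 5 FPKM or more in every anther library and under 0.5 FPKM in every callus library. The same rule gave 2 loci for 40D, 0 for NEC and 1 for EC. It is stricter for callus types, which resemble each other: SG NEC and SG 40D correlated at 0.943. Loci high in NEC had a median of 5.59% of their NEC level in SG EC replicate 1. Those high in EC had 4.47% of their EC level in SG NEC replicate 2. Such signal can make an abundant locus fail the rule, so the counts do not show that callus types lack loci of their own.

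Some loci were seen in 1 cultivar only, at 1 FPKM or more in its 12 libraries and at 0.1 FPKM or less in the 12 of the other. There were 17 for CS and 20 for SG. VIT_04s0008g03700 had 303 FPKM in CS anthers, 181 in 40D, 201 in NEC and 55.7 in EC, and was listed at 0 in all SG libraries. A hypothesis is that neighbouring loci are missing together, as a deleted or diverged stretch of the genome may give. The 37 loci held 3 pairs of neighbours in 2 places, since 2 of the pairs came from a run of 3 loci. The pairs were seen in the list before they were counted, so their number does not test the hypothesis, which stays open. Reads too diverged to align and loci absent from the genome were not told apart.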
